A study of Mus musculus with 8 samples.

How the data were processed

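RNA of CD11b+Gr-1+ myeloid cells from mouse bone marrow and colon tumors was hybridised as biotin-labelled cRNA to Affymetrix arrays. The deposited values of the authors were log2 expression values of 45101 probe sets made with GCRMA, which corrects background, normalizes between arrays and summarises probes, per the submitters' processing notes. The log2 scale was read from the values, which run from under 1 to over 15. The software, its version and any detection calls are not given in the sources used here. Array depth does not apply, so precision was limited by the number of arrays.

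Each array was placed in its group by its title, giving 4 groups of 2 arrays that the labels call technical replicates: wild-type bone marrow, HDC-KO bone marrow, wild-type tumor and HDC-KO tumor. Each group was therefore 1 pool in every comparison. Same-numbered arrays were not linked by the labels to a shared animal or day.

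Probe sets were named from the platform annotation supplied with the values. Of them, 34958 had 1 gene symbol, 932 several and 9211 none; no gene was named from the latter groups. No symbol changed when Entrez identifiers were matched to the RefSeq genes of GRCm38.p6, and 204 probe sets had an identifier that was not matched. The array's own build is not given in the sources used here, so no coordinates are printed. For each of 18194 genes the probe set with the highest mean over the 8 arrays was kept, and the 8174 genes with at least 2 arrays at or above log2 5 were tested. Some list genes were not analysed here and are not reported here.

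Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 8 arrays and 4 groups, with 4 residual and 2.14 prior degrees of freedom, so that the 4 pairs of technical arrays shared 1 estimate of the spread. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. The 5 contrasts were HDC-KO minus wild-type in bone marrow and in tumor, tumor minus bone marrow in wild-type and in HDC-KO, and the difference of the genotype effects. Errors of differences are limma's moderated standard errors, and errors of means are SDs of 2 technical arrays. Where a pool mean lay under log2 5, taken here as background, the fold is given as a bound with the mean raised to 5, and no fold is given where both lay under it.

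The genes named were chosen by a rule fixed before the data were examined. Hdc is always given. Per contrast, the rule takes the 6 largest and 6 smallest differences among called genes at or above log2 5 in both pools, and the 4 largest and 4 smallest bounds among called genes with 1 pool under it. For the difference of effects it takes the 5 largest and 5 smallest with all 4 pools at or above log2 5. From each gene list it takes up to 3 called members with the largest difference after means are raised, and predicted genes without a proper name are left out. Not every gene the rule takes is named. Those left out are described in the counts of their lists. H2-D1 and the genes of the closing observations were chosen after their values were seen.

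The 21 gene lists, fixed at the same time, covered histamine, primary and secondary granules, mature neutrophils, monocytes and macrophages, MHC class II and dendritic cells, suppressive function, cytokines and chemokines, cell cycle, interferon-induced genes, glycolysis and hypoxia, immediate early genes, matrix remodelling, myeloid transcription factors, basophils with mast cells and eosinophils, erythroid cells, epithelium, stroma, T and NK cells, B and plasma cells, and sex-linked genes. Gfi1 and Myb stand in both the primary granule and transcription factor lists, Irf8 and Klf4 in both the macrophage and transcription factor lists, and Cxcl10, Stat3 and Vegfa also in more than 1 list. Each list is described by its calls, its median, and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these pools. Counts adjusted over the list alone equalled those over all genes tested in each of the 100 pairs of list and contrast. Lists were examined with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

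The fit was tested on simulated data for HDC-KO against wild-type bone marrow with 8174 genes, where 97 of 100 genes changed by log2 1.5 and 100 of 100 changed by log2 2 were recovered, with 2 false calls. The simulated noise was that of technical arrays, and only genes with a mean at or above log2 5 were changed. These numbers therefore do not cover differences between mice or genes under that level. Alternatives were no filter, a filter at log2 7, values raised to log2 5, quantile normalization, median centring, the mean of or every probe set of a gene, only the groups compared, a trended and robust variance model, the replicate number as a block, averaged arrays without a test, and each array left out. Leaving out probe sets with identifiers ending in _x_at or _s_at was added after seeing the data. A planned pseudocount was not used because the values already were on the log2 scale. Because each group is a single pool, no comparison could be run without the pools whose values raise doubts.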

Results

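Gene expression was measured on 8 single-colour Affymetrix arrays of mouse myeloid cells sorted for CD11b and Gr-1, surface markers carried by granulocytes and monocytes. The mice either had or lacked Hdc, which encodes histidine decarboxylase, the enzyme that makes histamine. The bone marrow cells are described as HDC-expressing, read from an EGFP reporter, and came from 3 mice per genotype aged 3 to 4 months. The colon tumor cells came from 5 mice per genotype aged 7 months, after azoxymethane, a carcinogen, and dextran sodium sulfate, which injures the colon lining, and the labels name no EGFP gate for them. Each of the 4 groups was treated as 1 RNA pool on 2 technical arrays, so every adjusted p compares pools against the spread between technical arrays and says nothing of the spread between mice. The labels state pooling for the tumor cells and leave it open for bone marrow. On each array, 30.3% to 31.8% of the 45101 probe sets lay at or above log2 5, and across the 8174 tested genes the 2 arrays of a pool correlated at 0.996 to 0.998.

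The first check was Hdc itself. In bone marrow, Hdc fell from 13.18 ± 0.05 in the wild-type pool to 9.83 ± 0.06 in the HDC-KO pool (mean log2 value ± SD, n = 2 technical arrays), which was 10.2-fold lower (limma with Benjamini-Hochberg adjustment, adjusted p = 1.5e-06). In tumor, Hdc was 13.24 ± 0.01 in the wild-type pool and 13.03 ± 0.01 in the pool labelled HDC-KO, a log2 difference of -0.21 ± 0.05 (SE) that was under the 2-fold threshold (limma, adjusted p = 0.013). The other Hdc probe set gave log2 differences of -4.60 in bone marrow and -0.20 in tumor. The level of Hdc therefore went against the label of the HDC-KO tumor pool, and every direction drawn from that pool rests on its label alone. Of the 4 tested genes of histamine synthesis, transport, breakdown and reception, Hdc alone fell in the bone marrow comparison, and Slc18a2, a vesicular monoamine transporter, was called lower in the tumor comparison with both pool means under log2 5. The log2 difference of Slc18a2 there was -1.14, and it missed the threshold at -0.88 without array 1 of the pool labelled HDC-KO and at -0.98 without array 1 of the wild-type pool.

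**Figure D1:**
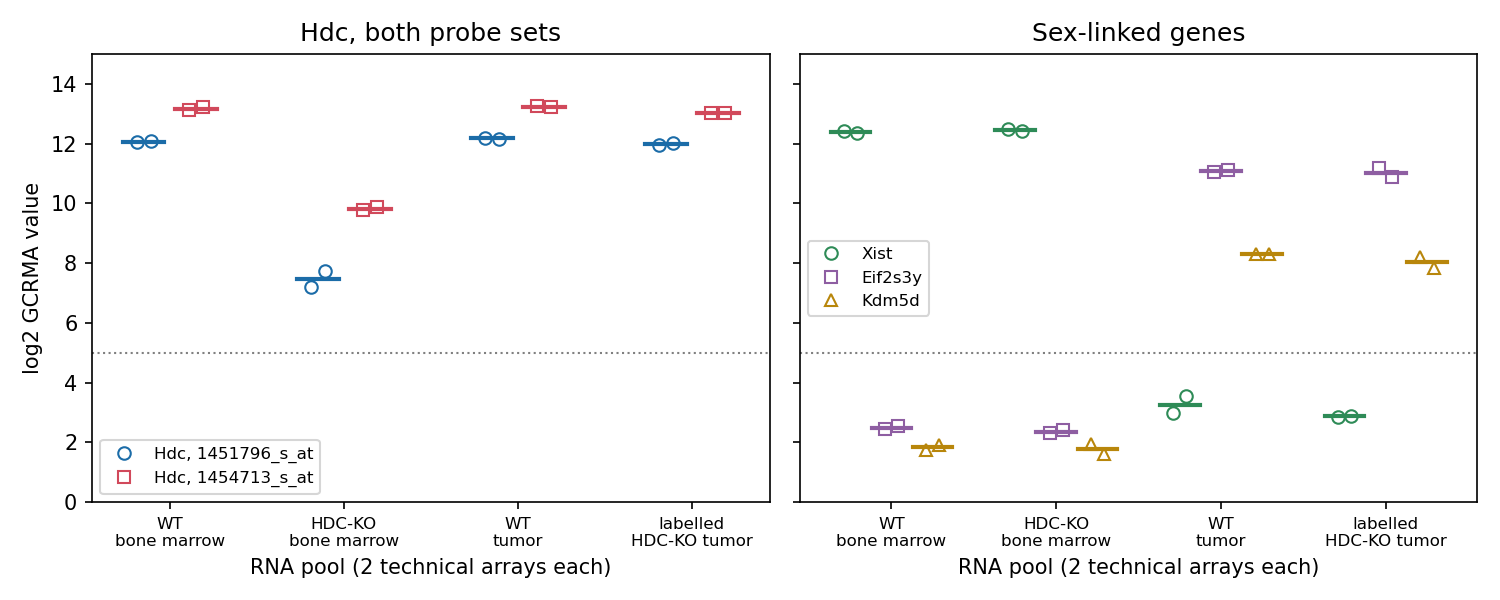
Log2 GCRMA values (vertical axis) of both Hdc probe sets (left) and of Xist, Eif2s3y and Kdm5d (right) on each array of the 4 RNA pools. Symbols are technical arrays, horizontal bars are pool means and the dotted line is log2 5; the brighter Hdc probe set read 9.83 in HDC-KO bone marrow and between 13.03 and 13.24 in the other pools.

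The first comparison set the HDC-KO bone marrow pool against the wild-type one. At some genes given below the wild-type bone marrow pool lay apart from every other pool, the wild-type tumor pool included. The differences between these pools can therefore not be assigned to the loss of Hdc alone. Igha and Jchain, 5 of 17 interferon-induced genes and 5 of 8 basophil, mast cell and eosinophil markers were lower in the HDC-KO bone marrow pool, while no gene of the granule and cell cycle lists passed the test. Igha, the immunoglobulin A heavy chain, fell by 5.65 ± 0.18 on the log2 scale (SE, n = 2 technical arrays per pool), which was 50.3-fold, and Jchain, which joins antibody units, fell 14.1-fold. Stat4, a transcription factor of interleukin 12 signalling, fell 22.1-fold, Tgm2, a transglutaminase, 12.9-fold, and Acod1, the enzyme that makes itaconate, 8.94-fold. Cd3d, a part of the T cell receptor complex, rose by 4.85 ± 0.14 on the log2 scale, and Ugt8a, an enzyme of galactosylceramide synthesis, by 4.20 ± 0.16. Of 8174 genes, 312 passed, 147 higher and 165 lower, in limma with Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. Both pool means lay under log2 5 for 26 of them.

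Among the other genes measured in both bone marrow pools, Ap1s3 rose 11.5-fold, Pik3ap1 8.58-fold, Ctse 7.10-fold and Lhx1 6.95-fold, although the other detected probe set of Ctse did not show a 2-fold rise. Of genes under log2 5 in the wild-type pool, Dsp, which encodes desmoplakin, was at least 22.3-fold higher, Fam71b at least 16.5-fold, Bend4 at least 11.3-fold and Erdr1 at least 10.7-fold. Of genes under log2 5 in the HDC-KO pool, Trim30d was at least 72.0-fold lower, Trim12a at least 54.8-fold and Ldhc at least 10.7-fold. The probe set annotated to Mir1931 was at least 18.6-fold lower, and whether it reads the microRNA itself was not checked. Trim12a, Mir1931 and Dsp, with Stat4, were among 6 genes at which, with means raised to log2 5, the wild-type bone marrow pool lay at least 16-fold from each of the other 3 pools. At H2-D1, a classical MHC class I gene, 3 probe sets lay at 3.72 to 4.65 in the wild-type bone marrow pool, under log2 5, and were higher by at least 7.02 on the log2 scale in the HDC-KO pool, while 4 others that reached log2 7 in a pool differed by -0.53 to -0.34. H2-D1 was chosen after its values were seen.

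Granulocyte genes did not pass the test between the bone marrow pools. None of the 10 primary granule genes of early granulocyte precursors, 15 secondary granule genes, 12 mature neutrophil genes, 21 cell cycle genes or 17 genes of glycolysis and hypoxia was called by limma. At an unadjusted p under 0.05, whatever their size, there were 5, 3, 8, 4 and 5 such genes. Counts adjusted over the list alone equalled those over all genes tested for every list and comparison. The median log2 difference of the primary granule genes was -0.30, at percentile 0.04 of 10000 random lists matched on expression, and that of the secondary granule genes was 0.02, with a mean of -0.02. The medians of the mature neutrophil, cell cycle and glycolysis lists were 0.07, -0.09 and -0.05, and the mean of the mature neutrophil list was -0.05.

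Interferon-induced genes and inflammatory genes fell in part in HDC-KO bone marrow. Of 17 interferon-induced genes 5 fell, led by Ifit1 at 5.55-fold, Oasl2 at 4.94-fold and Ifit3 at 3.87-fold, and 12 were not called. Of 23 cytokine and chemokine genes 6 were called lower, among them the neutrophil chemokine Cxcl2, which was at least 5.46-fold lower. For 3 of the 6, Cxcl3, Ccl3 and Ccl5, both pools lay under log2 5. Il1b and Csf1 were 2.12-fold lower each and missed the threshold when an array was left out, Il1b at a log2 difference of -0.99 without HDC-KO bone marrow array 1 and Csf1 at -0.94 without array 2. Of 18 immediate early and heat shock genes, which tissue dissociation also sets off, Fos fell 6.90-fold and Dusp1 3.05-fold. The medians of these 3 lists were -0.31, -0.30 and -0.21, each at or under percentile 0.02 of the random lists. With means raised to log2 5, the last 2 medians were 0.00.

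Markers of other cells moved as well between the bone marrow pools. Of 8 basophil, mast cell and eosinophil markers 5 fell, with a median of -1.54 (percentile 0.00), or -1.0 with means raised to log2 5. Mcpt8, a basophil protease, fell 4.23-fold, Fcer1a, the binding chain of the immunoglobulin E receptor, at least 2.26-fold, and Ms4a2, another chain of it, at least 2.04-fold. Of 17 monocyte and macrophage genes 5 rose and 2 fell, including Lpl at least 6.15-fold higher, Klf4 2.90-fold higher and Adgre1 3.30-fold lower, and Mertk was among the 5 with both pools under log2 5. Their median was 0.74 (percentile 100), or 0.00 with means raised to log2 5. Of 6 B and plasma cell markers 3 rose and 2 fell, with a median of 1.09, a mean of 0.05 and a median of 0.30 with means raised. Besides Jchain, Ighm fell 2.11-fold, which 1 of its 6 other detected probe sets did not show, and Cd79b rose 2.57-fold among them. Cd80 fell 2.88-fold among 10 MHC class II and dendritic cell genes, and of 16 intestinal epithelial genes Cdh1 was the 1 called, with both pools under log2 5, a list median of 0.02 and a mean of -0.04.

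Smaller groups gave few calls in bone marrow. Of 14 genes linked to suppressive function Cd274, the ligand PD-L1, was at least 2.60-fold lower and Ptgs2, the inducible cyclooxygenase, at least 1.14-fold. The list median was 0.01 and its mean -0.30, and Ptgs2 missed the threshold at -0.88 as the mean of its probe sets. Plau, the urokinase, rose 3.32-fold and Thbs1, thrombospondin 1, fell 3.08-fold among 10 matrix remodelling genes, and among 14 myeloid transcription factors Klf4 and Cebpa rose, Cebpa 2.31-fold, while Cebpb fell 2.17-fold. Of 3 erythroid markers Slc4a1 fell, at least 1.40-fold, and missed the threshold at -0.68 as the mean of its probe sets. Of 7 T and NK cell markers 2 rose and 1 fell. Cd3d was one of them. Nkg7, at a log2 difference of -1.06, was not called at -0.83 without wild-type bone marrow array 1, nor at -1.05 and -1.07 without HDC-KO array 1 or 2, where its limma adjusted p was 0.074, the highest over its alternatives. Gzma, at 1.02 with both pools under log2 5, was called when wild-type bone marrow array 1 was left out and not when any of the other 7 arrays was, with 0.64 the smallest difference. None of the 4 tested sex-linked genes was called by limma between the bone marrow pools or between the tumor pools, with 0 at an unadjusted p under 0.05 in each.

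The second comparison set the 2 tumor pools against each other. In the pool labelled HDC-KO tumor, granulocyte precursor and cell cycle genes were lower than in the wild-type tumor pool, and macrophage, MHC class II, interferon-induced and epithelial genes were higher. All 10 primary granule genes fell (median -2.74, or -2.67 with means raised to log2 5, percentile 0.00), including Mpo, the myeloperoxidase of azurophil granules, by 5.07 ± 0.07 on the log2 scale (SE, n = 2 technical arrays per pool), which was 33.7-fold. Of 21 cell cycle genes 20 fell (median -2.66, percentile 0.00), including Aurkb 17.3-fold, Bub1 16.6-fold and Cdk1 13.3-fold. Of 16 intestinal epithelial markers 15 rose (median 2.52, percentile 100), including Cldn3, a tight junction protein, 20.8-fold and Vil1, the brush border protein villin, 20.1-fold. Of 8174 genes, 2122 passed in limma with Benjamini-Hochberg adjustment, 1264 higher and 858 lower. Hdc did not differ by 2-fold between these pools, so the label of the HDC-KO pool was not borne out by its target gene.

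Genes measured in both tumor pools with the largest rises were Ccl5, a chemokine of T cells, at 27.5-fold, Tspan1 at 27.0-fold and Aldh1a1, a retinaldehyde dehydrogenase, at 26.6-fold. Abcb1a, a drug efflux pump, rose 24.7-fold, Myo15b 24.3-fold and Reg3b, an intestinal antimicrobial lectin, 22.3-fold. After Mpo, the largest falls were those of Olfml2b at 28.1-fold, Cenpf at 22.1-fold, Nuf2 at 20.9-fold, Depdc1b at 20.2-fold and Lbp, the lipopolysaccharide-binding protein, at 18.8-fold. Cenpf and Nuf2 act at the kinetochore, which attaches chromosomes to the spindle. Of genes under log2 5 in the wild-type pool, Ces2a, a carboxylesterase, was at least 56.7-fold higher, Prss30 at least 32.3-fold, Sdcbp2 at least 29.2-fold and Sptssb at least 29.2-fold. Of genes under log2 5 in the pool labelled HDC-KO, the spindle gene Aspm was at least 18.1-fold lower, Panct2 at least 16.6-fold, the kinetochore motor Cenpe at least 15.4-fold and Ctsg, the granule protease cathepsin G, at least 15.3-fold.

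Of 15 secondary granule genes 4 fell, led by Fcnb, a granule lectin, at 16.9-fold and Padi4, a histone-modifying enzyme, at 3.98-fold, and the list median was -0.73 (percentile 0.03). None of the 12 mature neutrophil genes was called by limma, 11 had an unadjusted p under 0.05, and their median was 0.16 (percentile 97.22). Of 14 genes linked to suppressive function of myeloid cells Tgfb1, transforming growth factor beta 1, was the 1 called, at 2.08-fold higher, and the list median was -0.03. The log2 difference of Tgfb1 was 0.99 without array 2 of the pool labelled HDC-KO, 0.94 without array 2 of the wild-type pool, 0.98 after quantile normalization and 0.66 as the mean of its probe sets, each under the threshold. Of 10 matrix remodelling genes 4 fell and 1 rose, including Mmp14, a membrane-bound metalloprotease, which fell 4.69-fold, and Plau, the urokinase, which fell 4.00-fold.

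Monocyte, macrophage and antigen presentation genes rose together with the epithelial markers. Of 17 monocyte and macrophage genes 12 rose (median 1.32, percentile 100), including the phagocytic receptor Mertk 11.9-fold, and of 10 MHC class II and dendritic cell genes 9 rose (median 2.11, or 2.08 with means raised, percentile 100), including H2-Ab1 5.12-fold and Cd40 5.33-fold. Of 17 interferon-induced genes 12 rose (median 1.59, percentile 100), led by Mx1 at 8.52-fold, Ifit3 at 7.71-fold and Oasl2 at 6.53-fold. Of 14 myeloid transcription factors 6 rose and 2 fell, with Irf5 5.78-fold higher and Gfi1, a repressor needed for granulocytes, 13.5-fold lower. Of 6 B and plasma cell markers 4 rose, including Cd79b 14.2-fold, and of 7 T and NK cell markers 5 rose and 1 fell, including Gzma, a cytotoxic granule protease, 11.3-fold higher and Cd3d 3.38-fold lower. Of 23 cytokine and chemokine genes 4 rose and 2 fell, with a median of 0.09 at percentile 12.96, and Csf1 was 2.44-fold higher. Of 17 glycolysis and hypoxia genes 5 rose and 1 fell, and P4ha1 and Egln3 missed the threshold at 0.71 and 0.87 as the mean of their probe sets. Ero1a was the 1 that fell, 2.67-fold, which 1 of its 2 other detected probe sets did not show. Of 18 immediate early genes Jun was the 1 called, at 2.97-fold higher, and its other detected probe set did not show a 2-fold rise.

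The 3 tested erythroid markers also rose, but Car1 is a colon epithelial gene too and was 4.24-fold higher. Slc4a1 was 5.07-fold higher, and Alas2 was at least 1.51-fold higher and missed the threshold at 0.59 with values raised to log2 5. Of 8 basophil, mast cell and eosinophil markers 2 rose and 1 fell, with Ccr3, the eotaxin receptor, at least 5.67-fold higher and Prg2, an eosinophil granule protein, at least 3.24-fold lower. Their median was 0.68 at percentile 30.95, or 0.00 with means raised to log2 5. The other one that rose was Kit, with both pools under log2 5, whose log2 difference of 1.10 was 0.67 without array 1 of the pool labelled HDC-KO and missed the threshold. None of the 12 fibroblast and endothelial markers reached the level needed for testing in any comparison.

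**Figure D2:**
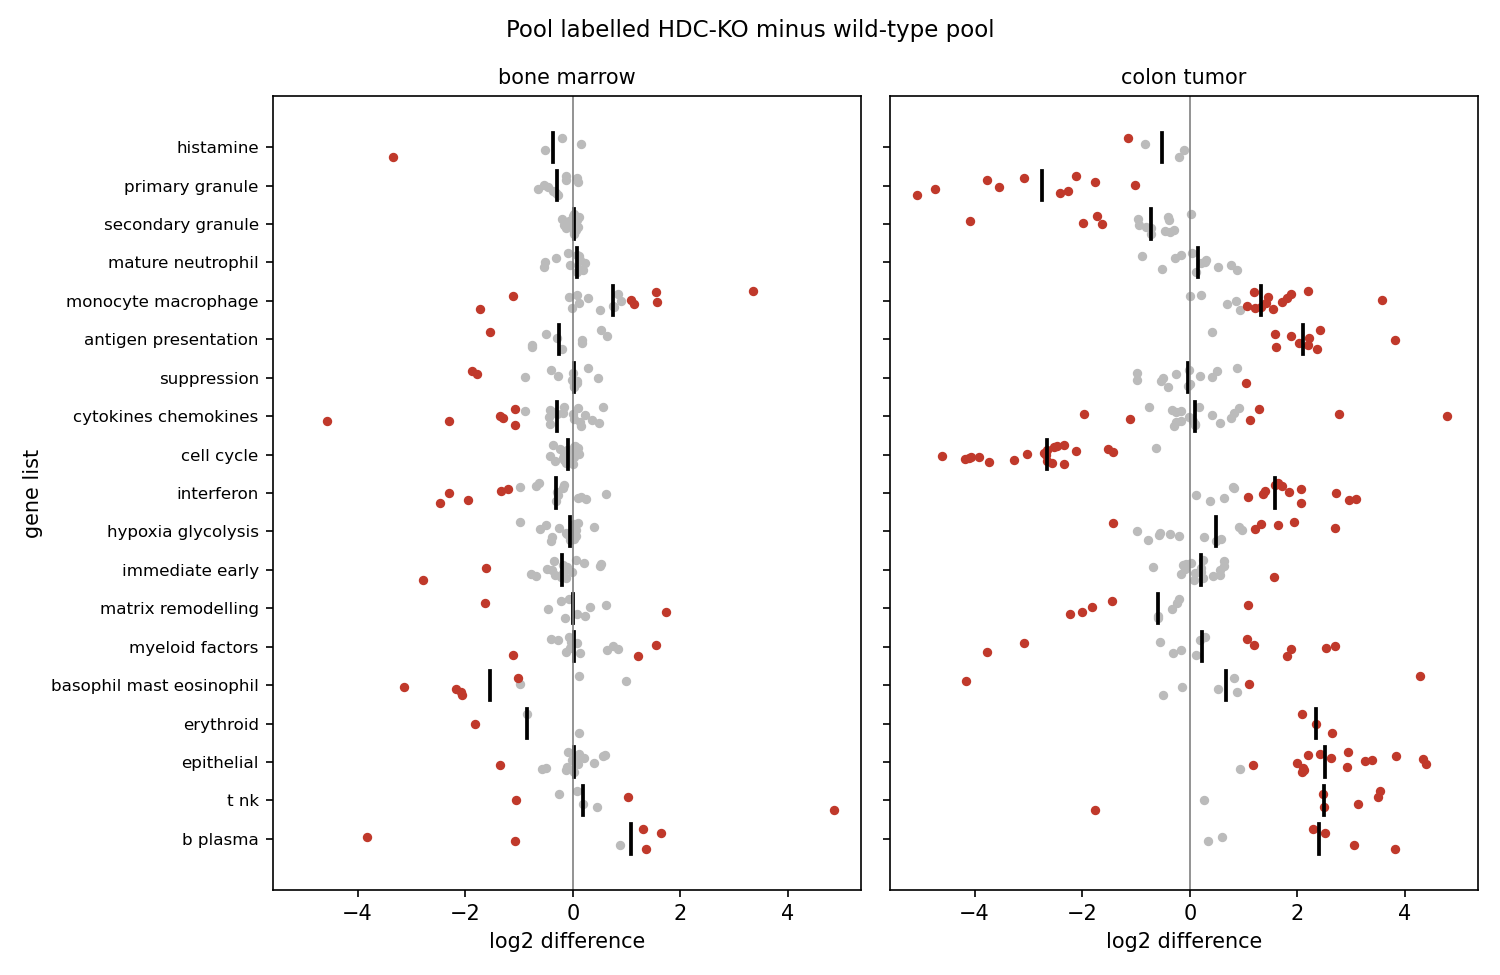
Log2 difference (horizontal axis) of each tested gene of the lists fixed in advance (vertical axis), HDC-KO minus wild-type, in bone marrow (left) and colon tumor (right, by label). Red points passed the test, grey points did not, and black bars are list medians; the primary granule median was -0.30 in bone marrow and -2.74 in tumor.

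The difference between these effects was tested directly, tumor minus bone marrow. Oasl2, an interferon-induced gene, fell in HDC-KO bone marrow and rose in the pool labelled HDC-KO tumor, with a difference of effects of 5.01 ± 0.17 on the log2 scale (SE, n = 2 technical arrays per pool). Igha had a difference of 6.58 ± 0.26, Ifit3 of 4.90 ± 0.22, Ifit1 of 4.54 ± 0.09 and Jchain of 4.41 ± 0.11. Ugt8a, at -7.04 ± 0.23, and Cd3d, at -6.60 ± 0.20, rose in bone marrow and fell in tumor, and Olfml2b, Mpo and Depdc1b had differences of -5.40 ± 0.20, -4.80 ± 0.09 and -4.56 ± 0.24. Of 17 interferon-induced genes the difference was called for 12, each higher. The difference passed for 2330 genes in limma with Benjamini-Hochberg adjustment, 1373 higher and 957 lower. Across genes, which are not independent replicates, the effects correlated at r = 0.012 (Spearman's rho 0.017). Of the genes called, 49 were higher in both comparisons (22.7 from independent lists, Fisher's exact p = 5.1e-08, two-sided) and 12 were lower in both (17.3 from independent lists, Fisher's exact p = 0.20). A further 29 were higher in bone marrow and lower in tumor and 40 the other way, against 15.4 and 25.5 from independent lists (Fisher's exact p = 0.00091 and 0.0031). These Fisher tests also treat genes as independent, which they are not. The excess of genes higher in both stood beside excesses in both opposite directions, so it does not by itself show a shared effect.

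The third comparison set wild-type tumor cells against wild-type bone marrow cells. Inflammatory, macrophage and epithelial genes were higher in the wild-type tumor pool, and primary granule genes were lower. Ptgs2, the inducible cyclooxygenase, rose by 8.11 ± 0.06 on the log2 scale (SE, n = 2 technical arrays per pool), which was 276-fold, and Cxcl2 rose 79.2-fold. Apoe, apolipoprotein E, rose 106-fold, C1qb, a complement C1q chain, 46.6-fold and Ccrl2, a chemerin-binding receptor, 184-fold. Rab44 fell by 4.65 ± 0.10 on the log2 scale, the interferon-induced Oasl2 by 4.08 ± 0.12 and the receptor activity-modifying Ramp1 by 4.04 ± 0.10. Of 8174 genes, 1338 passed in limma with Benjamini-Hochberg adjustment, 945 higher and 393 lower, and both means lay under log2 5 for 206 of them. Sex, age and the EGFP gate changed along with the tissue. The tumor mice had also been given azoxymethane and dextran sodium sulfate. The wild-type bone marrow pool, which lay apart from every other pool at some genes, is the reference here. Xist, expressed from the inactive X chromosome, was 12.39 in the wild-type bone marrow pool and 3.26 in the wild-type tumor pool. The Y-linked Eif2s3y was 2.49 and 11.09.

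All 17 monocyte and macrophage genes rose between the wild-type pools (median 3.43, percentile 100, or 3.10 with means raised to log2 5). Of 23 cytokine and chemokine genes 22 rose (median 2.95, or 1.69 with means raised), including Cxcl3 at least 318-fold, Cxcl1 at least 89.8-fold and Ccl3 at least 81.4-fold. Of 18 immediate early and heat shock genes 15 rose (median 4.48, or 3.00 with means raised), including Egr1 at least 185-fold, Nr4a1 43.4-fold and Egr3 at least 45.6-fold. Tissue dissociation also sets off these genes, and its part in this rise was not tested. Of 14 genes linked to suppressive function 5 rose, among them Arg1, the arginase, at least 47.3-fold and Cd274, the ligand PD-L1, 8.18-fold. Of 10 MHC class II and dendritic cell genes 9 rose (median 2.78, or 2.47 with means raised), including H2-Eb1 at least 39.8-fold, and of 10 matrix remodelling genes 7 rose, including the collagenase Mmp13 at least 19.9-fold. All 16 epithelial markers rose (median 4.70, or 2.67 with means raised), including Krt8 at least 33.1-fold and Epcam at least 25-fold. Krt8 reached 10.05 and Epcam 9.64 in the wild-type tumor pool. Which of the other rises came from the myeloid cells was not tested. Both pools lay under log2 5 for 2 of the cytokine and chemokine genes, 2 of the epithelial markers and 1 of the MHC class II and dendritic cell genes counted as higher. Ms4a6d was at least 129-fold higher and H2-Ea, an MHC class II chain, at least 91.8-fold.

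Of 10 primary granule genes 8 fell between the wild-type pools (median -1.64, percentile 0.00), including Elane 13.4-fold and Ctsg 9.68-fold. None of the 15 secondary granule, 12 mature neutrophil and 21 cell cycle genes was called by limma, with 5, 8 and 18 at an unadjusted p under 0.05. Their medians were -0.06, 0.08 and -0.36. Of 8 basophil, mast cell and eosinophil markers 6 fell and 1 rose (median -2.71, or -1.10 with means raised), including Mcpt8 at least 30.9-fold lower, and Ccr3, the 1 called higher, lay under log2 5 in both pools. Among interferon-induced genes 4 rose and 5 fell of 17, and among myeloid transcription factors 3 rose and 3 fell of 14, including Runx1 at least 18-fold lower, which 1 of its 2 other detected probe sets did not show. Of 6 B and plasma cell markers 4 rose, and of 7 T and NK cell markers 2 rose and 1 fell. Trim30d was at least 72.0-fold lower and Trim12a at least 54.8-fold, as they were between the bone marrow pools, and H2-Q10, an MHC class I relative, was at least 62.4-fold lower. Cd300ld fell 15.9-fold, Elovl7 15.9-fold and Rpgrip1 14.6-fold.

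The fourth comparison set the pool labelled HDC-KO tumor against HDC-KO bone marrow. Mpo fell by 7.69 ± 0.07 on the log2 scale (SE, n = 2 technical arrays per pool), which was 206-fold, and Igha rose by 8.65 ± 0.18, or 403-fold. Jchain rose 252-fold, Apoe 103-fold, Adgre4 95.2-fold, Cd14, a lipopolysaccharide co-receptor, 94.2-fold and Acod1 92.0-fold. Hdc rose 9.19-fold, toward the wild-type level. After Mpo, Itgb2l fell 46.8-fold, Olfml2b 33.0-fold, Ncam1 32.4-fold, Rasl11b 29.9-fold and Ms4a3 25.8-fold. Cxcl2 was at least 450-fold higher, H2-Ea at least 293-fold, Lypd8 at least 289-fold and Car1 at least 287-fold. Ctsg was at least 94.6-fold lower, H2-Q10 at least 33.5-fold and Slc27a2, a fatty acid transporter, at least 28.9-fold. Of 8174 genes, 2986 passed in limma with Benjamini-Hochberg adjustment, 1725 higher and 1261 lower. Xist and Eif2s3y again differed with the tissue, at 12.46 and 2.37 in bone marrow and 2.88 and 11.03 in tumor.

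In the pools labelled HDC-KO, all 17 monocyte and macrophage genes rose (median 4.94, or 4.44 with means raised to log2 5), as did 21 of 23 cytokine and chemokine genes (median 3.67, or 2.63) and 16 of 18 immediate early genes (median 4.71, or 3.78). Both pools lay under log2 5 for 1 of those cytokine and chemokine genes. The part of tissue dissociation in the rise of the immediate early genes was again not tested. All 16 epithelial markers and all 10 MHC class II and dendritic cell genes rose, with medians of 7.90 and 4.62, or 5.53 and 3.89 with means raised. All 10 primary granule genes fell (median -4.38), as did 20 of 21 cell cycle genes (median -3.01) and 6 of 15 secondary granule genes (median -0.82). Of 12 mature neutrophil genes 2 rose and 1 fell, with a median of 0.10, and Trem3, the 1 that fell, was at -1.02, or -0.997 without array 1 of this tumor pool and then under the threshold. Of 17 interferon-induced genes 11 rose, of 6 B and plasma cell markers 5 rose, and of 7 T and NK cell markers 5 rose and 2 fell. The T and NK cell median was 3.73, or 1.26 with means raised to log2 5 and -1.52 over the members left by a filter at log2 7. Sex-linked genes differed as they did between the wild-type pools, with 3 of 4 higher and Xist lower. Of the genes called between the wild-type pools, 849 were higher in both tissue comparisons and 220 lower in both, against 199.4 and 60.6 from independent lists, while 19 and 19 went opposite ways. The tissue effects correlated across genes, which are not independent replicates, at r = 0.754 (Spearman's rho 0.657). Over tested genes, array medians lay 0.13 higher on the log2 scale in this tumor pool than in its bone marrow pool.

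**Figure D3:**
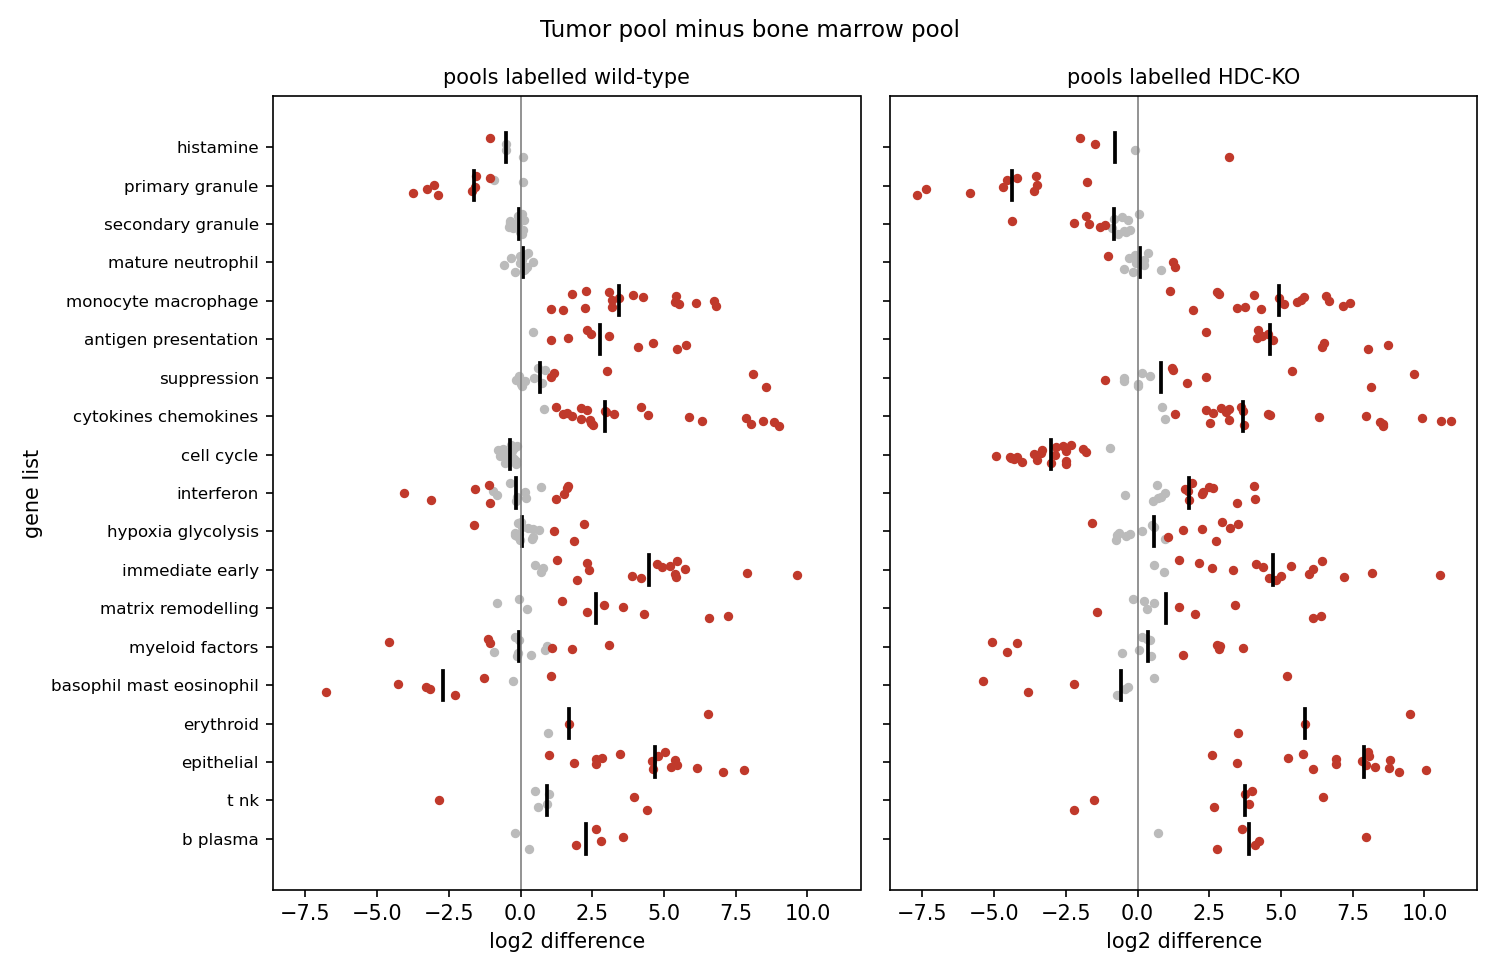
Log2 difference (horizontal axis) of each tested gene of the lists fixed in advance (vertical axis), tumor minus bone marrow, in the pools labelled wild-type (left) and HDC-KO (right). Red points passed the test, grey points did not, and black bars are list medians; the cell cycle median was -0.36 for wild-type and -3.01 for HDC-KO.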

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

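All tests of explanations except those of a different genetic background and of quantile normalization were chosen after the result was seen. The rule for reading the background test was also changed after its value was seen, from a comparison of the value alone with its bound of 10 percentage points to a comparison of the interval's upper limit.

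The difference between the pools labelled HDC-KO and wild-type was not the same in tumor and bone marrow for 2330 genes, by a test of the difference itself. That is 28.5% of the 8174 tested genes. Of 129 tested genes named in the report, the difference, on the log2 scale and as tumor minus bone marrow, was called for 105, 68 higher and 37 lower. The rule names genes for large differences on these same arrays, so a high share among them was built in and is no result. Fitted values of genes with a pool under log2 5 are no bounds. Each rests on the label of the HDC-KO tumor pool and on the wild-type bone marrow pool, which lay apart at some genes. Sex, age and the EGFP gate also changed with the tissue.

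Differences that were positive, with all 4 pools at or above log2 5, were Igha 6.58, Oasl2 5.01, Ifit3 4.90, Ifit1 4.54, Jchain 4.41, Tgm2 3.69, Adgre1 3.26, Hdc 3.14, Acod1 3.00, Fos 2.86, Ramp1 2.67 and Elovl7 2.65. Further positive ones were Irf5 2.59, Cd79b 2.46, Csf1 2.37, Cd80 1.94, Egln3 1.82, Dusp1 1.81, Adgre4 1.77, Ighm 1.42, Thbs1 1.39, Nkg7 1.32, P4ha1 1.31 and Cebpb 1.24. Further positive ones were Il1b 1.18 and Cd14 1.13. Differences that were positive, with a pool under log2 5, were Trim30d 10.44, Trim12a 8.22, Mir1931 6.33, Ccl5 6.14, Ces2a 6.06, Sptssb 5.72, Aldh1a1 5.34, Prss30 5.05, Sdcbp2 4.71, Cxcl2 4.61, Tspan1 4.56 and Stat4 4.50. Further positive ones were Abcb1a 4.38, Myo15b 4.36, Cldn3 4.29, Vil1 4.27, Ccr3 4.16, Slc4a1 4.15, Reg3b 4.10, Fcer1a 2.98, Mcpt8 2.95, H2-Eb1 2.95, Car1 2.94 and Mx1 2.84. Further positive ones were Ms4a2 2.70, Ldhc 2.57, H2-Ab1 2.57, Alas2 2.54, Cdh1 2.53, Mertk 2.50, Gzma 2.48, Cd274 2.36, Lypd8 2.33, Krt8 2.26, Cxcl3 2.14 and Kit 2.09. Further positive ones were Epcam 2.06, Ccl3 2.05, Cd40 1.90, Jun 1.79, Ptgs2 1.52 and Ccrl2 1.30.

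Differences that were negative, with all 4 pools at or above log2 5, were Ugt8a -7.04, Cd3d -6.60, Olfml2b -5.40, Mpo -4.80, Depdc1b -4.56, Nuf2 -4.33, Ap1s3 -4.31, Cenpf -4.30, Ncam1 -4.09, Fcnb -4.01, Bub1 -3.97 and Aurkb -3.93. Further negative ones were Plau -3.73, Itgb2l -3.67, Lbp -3.66, Cdk1 -3.64, Gfi1 -3.63, Ctse -3.50, Ms4a3 -3.10, Pik3ap1 -2.88, Rasl11b -2.28, Padi4 -1.85 and Ero1a -1.51. Differences that were negative, with a pool under log2 5, were Fam71b -5.78, Prg2 -5.13, Panct2 -4.44, Aspm -4.18, Ctsg -4.09, Bend4 -4.02, Cenpe -3.86, Dsp -3.73, Erdr1 -3.63, Lhx1 -3.10, Ms4a6d -3.08 and Mmp14 -2.31. Further negative ones were Elane -2.09 and Lpl -1.15.

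The level of Hdc in the pool labelled HDC-KO tumor was the first pattern weighed. Whether the probe sets lie outside the deleted part stays open. Both fell in HDC-KO bone marrow, the smaller drop being -3.35, so both responded to the knockout there. The drop cannot place them inside the deleted part, since they still read 9.83 and 7.47 in that pool. A pool that did not come from HDC-null mice is a candidate explanation, since both probe sets lay near the wild-type tumor level, the larger difference being -0.21. Transcription from the knockout allele may also contribute and cannot be told apart from a wrong label, because Hdc in HDC-KO bone marrow, at 9.83, stayed above log2 5.

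The second pattern was the wild-type bone marrow pool standing apart from each other pool by 4 or more log2 units at 9 genes, or at 6 with means raised to log2 5. A single scaling factor for the array is argued against, since the pool was lower at 2 of the 9 (1 of the 6) and higher at the rest. After quantile normalization 100% of the 9 stayed called, at differences of 4.36 or more between the bone marrow pools. That result carries no weight, since the 9 were picked for lying 4 or more log2 units apart and moved by at most 0.10. The sex of the mice is argued against by sex-linked genes, which differed by at most 0.13, and loss of Hdc alone by the wild-type tumor pool, which kept Hdc at 13.24, while loss of Hdc in one tissue with a tissue difference in the other stays open and untested. A different MHC haplotype in this pool is a candidate explanation, since 3 H2-D1 probe sets moved by 7.37 or more, or by at least 7.02 with means raised to log2 5, while others stayed. A different MHC haplotype would itself be a difference of genetic background. Whether the background differed more widely stays open. The test took called genes at log2 7 or more in a pool and their other probe sets at that level. It could not see H2-D1, whose kept probe set differed by -0.34 and was not called. Of 41 such probe sets, 9.8% did not move the same way by 0.5 on the log2 scale. In tumor the share was 2.6% of 469 (Fisher's exact p = 0.032, two-sided). The difference was 7.2 percentage points, and its 95% Newcombe interval, 1.1 to 20, passed the bound of 10.

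The third pattern was the rise of other-cell markers and fall of precursor genes in the pool labelled HDC-KO tumor. A smaller share of granulocytes alone is argued against for the fall of precursor genes, since it would lower mature neutrophil genes too. None of 12 mature neutrophil genes was called. Their median was 0.16, against -2.74 for primary granule and -2.66 for cell cycle genes. For the rise of other-cell markers, a smaller share of granulocytes stays open. To weigh that rise, medians were compared among members at or above log2 5 in both tumor pools. There, 14 epithelial markers exceeded 17 macrophage genes by 1.45 in median log2 difference (permutation p = 0.0023, two-sided, over genes that are not independent). This gap cannot decide whether a smaller share made the rise, since genes that the sorted cells carry themselves would rise less. In both bone marrow pools, 9 of 17 macrophage genes but 1 of 16 epithelial markers lay at or above log2 5. Carried-over epithelial cells as the only change are argued against, since 70.6% of tested macrophage genes rose too. Fewer cycling precursors and lower expression within them cannot be told apart, since a change in cell shares gives the same values; among members at or above log2 5 in both tumor pools the smaller drop of a median below that of 12 mature neutrophil genes was -2.72 (permutation p = 8e-05 for 17 cell cycle genes and exact permutation p = 0.0022 for 7 primary granule genes). Any effect of the genotype stays open and untested, because the label of the pool is in doubt.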

How the results depend on the processing

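Leaving out probe sets with identifiers ending in _x_at or _s_at was chosen after the data were seen; the other alternatives were fixed before the data were examined. Of the counts of genes called, 94 stayed within 1.5 times the reported count. Testing every probe set on its own called 502 probe sets between the bone marrow pools, 3300 between the tumor pools, 2147 between the wild-type tissues, 4898 between the tissues labelled HDC-KO and 3728 for the difference of effects, because 13505 probe sets were tested in place of 8174 genes. Of values of named genes, 4278 kept their direction and call and 40 lost the call, 4 of them at a difference of 0.00 to 2 decimals with values raised to log2 5 (Slc18a2 between the tumor pools and between the tissues labelled HDC-KO, Cdh1 and Gzma between the bone marrow pools). List medians stayed within the spread in 840 cases and moved in 267. The T and NK cell median between the tissues labelled HDC-KO, 3.73, turned to -1.5194 with a filter at log2 7, which leaves fewer members; 2 of 7 had fallen. Without a test, averaged arrays gave 313 and 2122 genes at least 2-fold apart in the genotype comparisons, against 312 and 2122 called, so the threshold of size set nearly all counts. Leaving out each array gave 286 to 311 genes between the bone marrow pools, 2122 to 2140 between the tumor pools, 1333 to 1344 between the wild-type tissues, 2986 to 3011 between the tissues labelled HDC-KO and 2306 to 2348 for the difference of effects, the lone array being assumed to vary like the other groups. With the replicate number as a block, the counts were 312, 2122, 1339, 2986 and 2327; same-numbered arrays deviated together at r from -0.0147 to 0.0575, so the numbers do not pair the arrays. A pseudocount was not run, as the values were log2 already. Pools in doubt could not be left out of their own comparisons. Levels under log2 5 could not be told from background, and fitted log2 differences that involve them are no bounds.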

Other observations

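These observations were chosen after the values were seen, and no test of an explanation was run for them.

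The mast cell proteases Mcpt1 and Mcpt2 differed between the tumor pools. Mcpt1 was 8.35 ± 0.02 and Mcpt2 8.87 ± 0.17 in the wild-type tumor pool (mean log2 value ± SD, n = 2 technical arrays), against 2.59 ± 0.21 and 2.57 ± 0.12 in the pool labelled HDC-KO tumor. Mcpt1 was thus at least 10.2-fold lower and Mcpt2 at least 14.7-fold lower in the latter. With means raised to log2 5, no gene lay at least 16-fold from each other pool in wild-type tumor, against 6 genes in wild-type bone marrow, 1 in HDC-KO bone marrow (Igha) and 46 in the pool labelled HDC-KO tumor.

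Some genes were high in both tumor pools and under log2 5 in both bone marrow pools. Ifi202b was 9.94 and 11.93 in the tumor pools labelled wild-type and HDC-KO against 2.80 and 2.73 in bone marrow, and Pla2g2a was 9.32 and 8.63 against 2.66 and 2.09. H2-Ea was 11.52 and 13.19 against 2.02 and 3.88. Its pattern was shared by other MHC class II genes, with H2-Ab1 at 10.16 and 12.51 against 4.70 and 4.49. H2-Eb1 was 10.31 and 12.50 against 4.54 and 3.78. Of the 10 tested MHC class II and dendritic cell genes, 9 rose between the wild-type pools and 10 between those labelled HDC-KO. All samples are labelled with the same strain, and the strain was not checked here by other means. The pattern shared with other MHC class II genes covers H2-Ea and not Ifi202b or Pla2g2a. Whether these differences between tissues reflect a difference of strain was not tested.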
